A study of Mus musculus with 14 samples.

How the data were processed

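Assay for transposase-accessible chromatin (ATAC-seq) had been done on sorted hippocampal neuronal nuclei from 14 samples of 4 groups. Per the labels' protocols, nuclei were stained for NeuN (a neuronal marker), Arc and GFP and sorted by fluorescence. The series' design text states that tissue of 10-12 mice was pooled to reach 10000 nuclei per condition, in 3 biological replicates; 4 libraries each are present for Basal and Late. The labels do not say for each library which mice it came from, so p-values measure the spread between these libraries, part of which can be technical.

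The authors deposited 1 table of 191271 regions with RPKM values (reads per kilobase of region, scaled to the library's read total) for the 14 libraries. Bowtie2 2.0, SAMtools, MACS2, DiffBind, DESeq2 and the mm9 build are named per the submitters' processing notes, which give no role or order for them. Whether regions were called per library or on pooled reads, whether duplicate reads were removed and whether cut positions were shifted is not given in the sources used here. Those steps set region borders and the number of reads at high regions. Coordinates are printed as the table gives them, and the last region of chromosome 1 ends at 197188942. Whether a start counts from 0 or 1 is not given in the sources used here.

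Multiplied by region length (end minus start), all deposited RPKM values came out as whole multiples of 1 step per library (100% within a tolerance of 0.01), so reads and the totals used for scaling were recovered. No value was 0. The lowest was 1 read, at which 2.27% to 3.11% of regions stood in each library, so regions without reads appear to be listed at 1 read. Totals were 46134253 to 56251676 reads, of which 7145415 to 15075081 fell in regions, with a median of 25 to 47 reads per region. The 95% Wilson interval of the share of reads in regions was at most 0.0119 percentage points to either side. Such intervals cover counting error only. Replicates were compared by a mean chi-square of their recovered reads per region (1 for sampling noise alone). It was 1.77 to 2.03 between Late libraries, and 2.35 to 6.75 between libraries of one group elsewhere. A value above 1 does not show separate biological samples, since separate preparations of one sample exceed 1 too. From the regions of lowest to those of highest level it changed by a factor of 0.912 to 1.18 in Late and 1.21 to 3.30 elsewhere. The Late libraries were counted as 4 samples because the labels list 4, and their average as 1 sample was an added alternative.

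Values were analysed as log2(RPKM + 0.5), a scale that understates the change of low regions. The 10% of regions with the lowest mean RPKM were left out, which left 172143. All 14 libraries entered 1 limma fit (limma 3.58.1 in R 4.3.3, intensity trend, robust) with group means, because groups of 3 or 4 give few residual degrees of freedom. The 6 comparisons were 2-sided, with Benjamini-Hochberg adjustment over regions within each and a threshold of 0.05. Errors of fold changes are limma's moderated standard errors, those of RPKM values the SD over libraries. Exact permutation tests compared library measures. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6 did the remaining steps.

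The rule for the positions named in the text was fixed before the data were examined. Among regions with adjusted p under 0.05, groups without overlap and a mean log2 value above the median, it took the 6 largest log2 fold changes up and the 6 down for Early against Basal, Late against Basal and Reactivated against Late, and 3 and 3 for the other comparisons. Chance puts 5.71% of regions in groups without overlap for 3 against 4 libraries, 2.86% for 4 against 4 and 10% for 3 against 3. The chromosomes described were chosen after their values were seen. The design fixed in advance also held gene lists, promoter classes and motifs. An annotation or sequence of the mm9 build was not used here, so these were not run. The gene table used was of another build (GRCm38.p6), had nothing to match on, and gave only numbers of protein-coding genes per chromosome.

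The test was checked on simulated reads for the 172143 regions with 50 regions changed per fold size. In Early against Basal it recovered 86% of 4-fold and 8% of 2-fold changes, in Late against Basal 92% and 26%, and in Reactivated against Late 90% and 16%. Changes of 1.25-fold and 1.5-fold were recovered in 0% of cases, and 2 to 3 unchanged regions passed per comparison. The pass mark first set for this check, over 90% of 4-fold changes recovered and under 60 false calls, was missed in recovery. It was then lowered to over 75% recovered, with false calls at most 10% of calls, and the fit was left as it was. The recovered shares hold for this simulation, in which few regions changed and the adjustment was therefore stricter than in comparisons with many calls. Comparisons that share the Basal libraries were set beside 20 simulated draws in which all groups had the same means, and beside Basal divided 2 and 2. Overlaps of calls with Basal or Late divided in this way, and without each library, were added after seeing the data.

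Alternatives fixed in advance were other pseudocounts (0.1 and 1), no filter, only regions above the median, quantile normalization, median-of-ratios scaling, a fit of only the groups compared, library quality weights, a replicate block, an added fold threshold of 1.5 and leaving out each library. Alternatives added after seeing the data were limma voom on recovered reads, Late averaged to 1 sample, the share of reads in regions as a covariate, and leaving out chrUn_random and chromosome Y. Count-model tools planned for count tables were not run, because the values are RPKM.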

Results

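Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in neuronal nuclei sorted from mouse hippocampus. The mice carried a tamoxifen-dependent Cre recombinase at the Arc locus and a floxed yellow fluorescent protein reporter, which marks cells in which Arc, an activity-induced gene of neurons, was active around the time of tamoxifen. Mice were trained in contextual fear conditioning with a foot shock on day 0. The 14 libraries form 4 groups by their titles, Basal (n = 4), Early (n = 3), Late (n = 4) and Reactivated (n = 3). Basal and Early carry the same treatment label (shock and collection on day 0, no recall) and differ in their titles only. The labels do not say what sets the Basal nuclei apart, such as handling or the sorted population, so a fold change against Basal is not shown to be a change over time. Late was collected on day 5 without recall, and Reactivated had recall on day 5 and collection labels of days 5, 6 and 7 for replicates 1, 2 and 3. The series describes its question as how accessibility differs between phases of memory. One common list of 191271 regions, on the mm9 build, gives an RPKM value per library. No gene names accompany the regions, so they are named here by position.

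Read totals recovered from the RPKM values were 54266315 to 54269492 in Basal, 54257745 to 54261749 in Early, 46134253 to 47375212 in Late and 54257222 to 56251676 in Reactivated. All totals but those of Late and Reactivated replicate 1 (56251676) thus lay between 54257222 and 54269492. Such near-equal totals need not be sequenced depths, and whether reads had been brought to a common total was not tested. The share of reads inside regions was 15.7% ± 2.71 in Basal (SD, n = 4), 19.9% ± 7.15 in Early (n = 3), 19.2% ± 0.653 in Late (n = 4) and 23.1% ± 1.54 in Reactivated (n = 3). Early replicates 1, 2 and 3 stood at 13.8%, 27.8% and 18.1%. None of the 6 differences between groups passed a 2-sided exact permutation test. Reactivated exceeded Late by 3.90 percentage points (exact permutation p = 0.0571, adjusted over 6 comparisons 0.171, higher in 3 of 3 libraries) and Basal by 7.35 (p = 0.0571, adjusted 0.171), and 0.0571 is the smallest p that 3 against 4 libraries allow. The highest values were compressed in Late: the RPKM exceeded by 0.1% of regions, divided by the median RPKM, was 4.23 ± 0.127 there, 7.93 ± 1.65 in Basal, 7.31 ± 1.78 in Early and 8.66 ± 0.455 in Reactivated. The difference of Late from Basal had an exact permutation p of 0.0286, the smallest that 4 against 4 libraries allow (adjusted over 6 comparisons 0.114). Of the 99 regions on chrUn_random, 69 to 72 held more than 1 read in each Late library and 0 did in the other 10 libraries. The highest value of any region was 0.635 to 0.738 reads per base in the Late libraries, with 0 regions over 2, and 2.14 to 9.75 in the other 10 libraries, with 1 to 6 regions over 2.

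**Figure D1:**
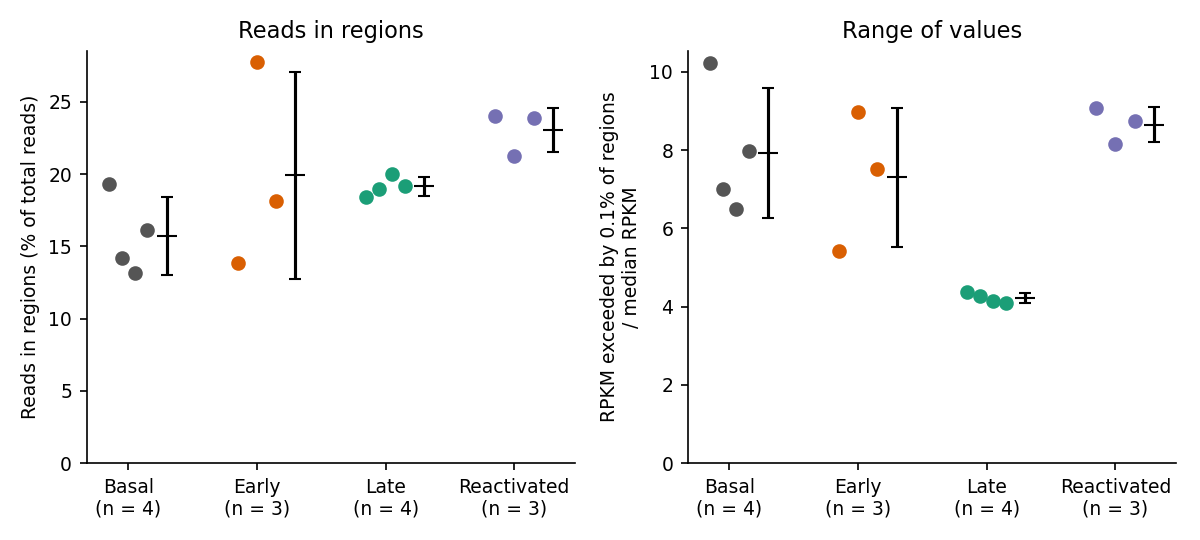
Share of reads inside regions (left, percent of total reads) and RPKM exceeded by 0.1% of regions divided by the median RPKM (right) for each of the 14 libraries by group; points are libraries and bars the mean ± SD. The Early libraries spread from 13.8% to 27.8%, and the 4 Late libraries lie below all others on the right, with a mean of 4.23.

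Libraries of one group mostly lay together. The first principal component of the log2 values held 45.7% of the variance and placed the Basal libraries from -204.44 to -95.85, Late from 59.60 to 93.56 and Reactivated from 66.54 to 119.21. The Early libraries were scattered along it, replicate 1 at -129.86, replicate 3 at -20.14 and replicate 2 at 198.08. This order is also that of their share of reads in regions (13.8%, 18.1% and 27.8%). Of all libraries, the lowest and highest on the component, Basal replicate 3 and Early replicate 2, had the lowest and highest share (13.2% and 27.8%). The share does not give the whole order: Basal replicate 1, with 19.3%, lay at -95.85 and Late replicate 1, with 18.4%, at 59.60. After median-of-ratios scaling the first component (37.5% of the variance) still separated Basal, at -162.38 to -117.31, from Late and Reactivated, at 48.59 to 92.74. Correlations of log2 values between libraries of one group were 0.673 to 0.739 in Basal, 0.656 to 0.693 in Late and 0.653 to 0.733 in Reactivated, and 0.382 to 0.608 in Early. Basal and Late libraries correlated at 0.104 to 0.371. These correlations are across regions, which are not independent replicates.

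**Figure D2:**
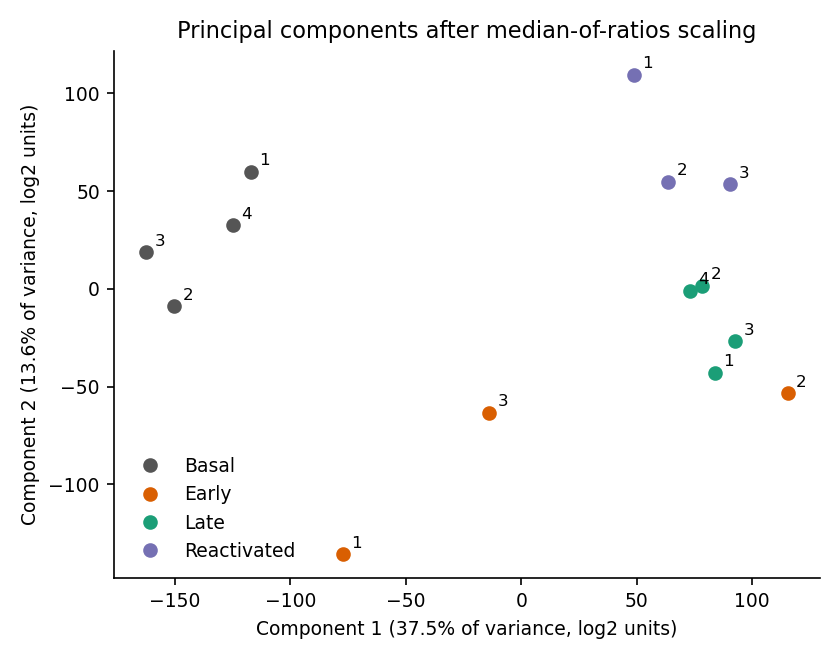
Scores of the 14 libraries on principal components 1 and 2 of log2(RPKM + 0.5) after median-of-ratios scaling, in log2 units, coloured by group and numbered by replicate. The 4 Basal libraries lie on the left and Late and Reactivated on the right, with the 3 Early libraries spread from -77.45 to 115.38 on component 1.

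Early and Basal were both labelled with collection on the conditioning day. The region with the largest rise was chr3:92226809-92227074, with 3.55 ± 2.07 RPKM in Early (SD, n = 3) against 0.278 ± 0.150 RPKM in Basal (n = 4; log2 fold change 2.27 ± 0.28 SE, adjusted p = 0.00229). It stood at 2.38 ± 0.340 RPKM in Late and 1.70 ± 0.222 RPKM in Reactivated. The wider region chr2:99171866-99172774 rose from 0.487 ± 0.151 to 4.53 ± 3.29 RPKM (log2 fold change 2.17 ± 0.31 SE, adjusted p = 0.00447). Without Early replicate 2, at 8.32 RPKM, its Early mean was 2.64 RPKM and its log2 fold change 1.68 (limma, adjusted p = 0.0247). The regions chr1:149166806-149167031, chr14:111048103-111048273, chr9:88164182-88164418 and chr3:110691792-110692046 rose by 2.06 to 2.20 on the log2 scale. Most of these rest on few reads, between 1 and 121 per library outside the region on chromosome 2, where the range was 17 to 410. Of the 6 regions with the largest falls, 3 lie on chromosome 7. The largest fall was at chr7:148748905-148749022, from 3.19 ± 0.817 RPKM in Basal to 0.368 ± 0.241 in Early (log2 fold change -2.10 ± 0.29 SE, adjusted p = 0.00378), with 2.33 ± 0.927 RPKM in Late and 2.79 ± 1.01 RPKM in Reactivated. Without Early replicate 3 its Early mean was 0.236 RPKM. The regions chr7:30102705-30102868 and chr7:51614856-51615006 fell by 1.87 and 1.77, and chr1:75500320-75500435, chr5:124564503-124564827 and chr2:148538786-148538946 fell by 1.67 to 1.71. These 12 regions kept their direction and their call under each of 28 alternative settings. They had been chosen from the same data as the largest called changes, so this stability follows in part from the choice. Some of the settings only left out libraries of groups not compared here.

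Across the 172143 tested regions, 18836 were higher and 2471 lower in Early (limma, Benjamini-Hochberg adjusted p under 0.05), and the median log2 fold change of all regions was 0.23. Median-of-ratios scaling gave 14081 higher and 11798 lower and quantile normalization 11356 and 10014. These scalings centre the fold changes, so the more even split follows largely from the centring. In all 3 scalings 10878 regions were higher and 2450 lower. Chromosome 7 had 487 lower and 50 higher among 3424 regions, a median of -0.25 (-0.49 after median-of-ratios scaling), and chromosome 17 had 223 lower and 200 higher among 3482, a median of -0.02 (after median-of-ratios scaling 20.97% lower and 4.25% higher, with a median of -0.25). Chromosome X had 702 higher and 7 lower among 3368 and a median of 0.49 (0.27 after median-of-ratios scaling). Per library, the median of chromosome 7 relative to the autosomes was -0.37 to -0.20 in Early and 0.11 to 0.25 in Basal, and that of chromosome 17 was -0.24 to -0.15 and 0.02 to 0.10 (log2 deviations from the mean of all libraries, exact permutation p = 0.0571 for each, the smallest that 3 against 4 libraries allow, adjusted over 18 tests 0.129). That of chromosome X was -0.16, 0.30 and -0.05 in Early replicates 1, 2 and 3 and -0.30 to -0.14 in Basal, a difference of means of 0.25, or 0.11 without Early replicate 2. The count depended on single libraries: it was 1227 without Early replicate 2, 46005 without Early replicate 1, and 11449, 8147 and 13340 without Basal replicates 2, 3 and 4. Averaging Late to 1 sample gave 10991, and a fit of the Early and Basal libraries alone 6370.

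**Figure D3:**
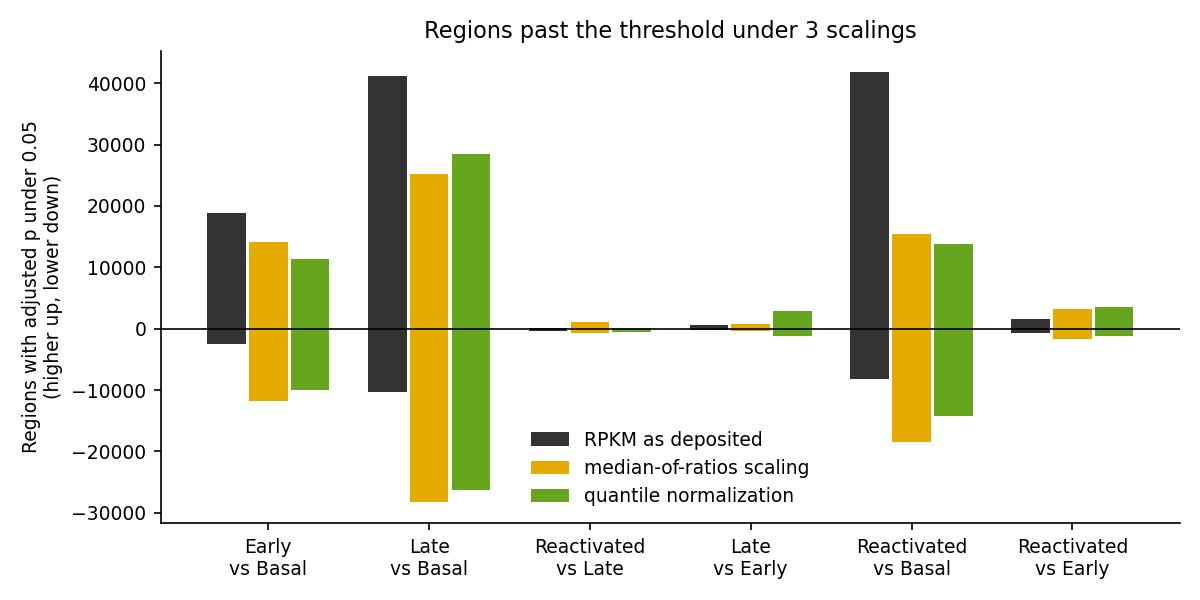
Number of regions with adjusted p under 0.05 in each of the 6 comparisons, higher regions above and lower regions below the zero line, for RPKM as deposited, median-of-ratios scaling and quantile normalization. On the deposited scale 18836 regions were higher and 2471 lower in Early than in Basal, against 14081 and 11798 after median-of-ratios scaling.

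The comparison of Late with Basal sets libraries collected on day 5 beside those labelled Basal. The largest rise was at chr1:20123128-20123410, with 3.28 ± 0.133 RPKM in Late (SD, n = 4) against 0.245 ± 0.0980 RPKM in Basal (n = 4; log2 fold change 2.35 ± 0.36 SE, adjusted p = 0.000362), and the same region stood at 3.14 ± 2.97 RPKM in Early (1.50 without Early replicate 2) and 3.31 ± 1.45 RPKM in Reactivated. On chromosome X, chrX:66335000-66335233 rose from 0.178 ± 0.150 RPKM (0.105 without Basal replicate 3) to 2.71 ± 0.381 RPKM (log2 fold change 2.26 ± 0.30 SE, adjusted p = 0.000188). The regions chr8:59363111-59363289, chr6:15055056-15055370, chr1:97731374-97731504 and chr16:61013030-61013187 rose by 2.23 to 2.30. All 6 rises rest on few reads, between 1 and 98 per library, with the lowest, in Basal, at 1 or 2 reads. The 6 largest falls were all at regions of very high value in the other groups. At chr2:98506396-98507470 the value was 47.7 ± 10.4 RPKM in Basal, 44.6 ± 4.51 RPKM in Early and 4.96 ± 0.325 RPKM in Late (log2 fold change -3.12 ± 0.32 SE, adjusted p = 3.05e-05). At chr17:39979978-39985726, 5748 bases long, it was 85.8 ± 6.83 RPKM in Basal and 14.6 ± 0.822 RPKM in Late (log2 fold change -2.51 ± 0.32 SE, adjusted p = 0.000149). The regions chrX:139917553-139917648, chr2:98502391-98503129, chr9:35112799-35113174 and chr2:98505160-98505368 fell by 2.21 to 2.40. The compressed range of the Late libraries, in which no region reached 2 reads per base, moves with these falls.

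In all, 41202 regions were higher and 10380 lower in Late than in Basal (limma, adjusted p under 0.05), with a median log2 fold change of 0.28. After median-of-ratios scaling 25189 were higher and 28183 lower, after quantile normalization 28443 and 26237, and 23388 higher and 10341 lower regions were shared by the 3 scalings. Chromosome X again had more rises, 1581 higher and 24 lower among 3368 regions with a median of 0.64. All 6 tested regions on chrUn_random were among the higher ones, but they stood at the floor of 1 read in each Basal library. Chromosome 7 had 383 higher and 187 lower and a median of 0.10 (after median-of-ratios scaling 5.29% higher and 21.50% lower, with a median of -0.19). With the 4 Late libraries averaged to 1 sample, which leaves the fold changes as they were (median 0.28) and takes the spread from the other groups, 0 regions passed in limma, with 24989 at an unadjusted p under 0.05. With the share of reads in regions as a covariate 31606 passed, 20038 higher and 11568 lower.

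The changes of Early and of Late against Basal overlapped. Of the 18836 regions higher in Early, 15922 were also higher in Late, where independent lists of these sizes would share 4508. The count rests on Early replicate 2, which correlated with the Late libraries at 0.633 to 0.689 and with Early replicate 1 at 0.382: without it 770 regions were higher in Early, 744 of them in Late as well (238 for independent lists). The number higher in both was 30821 without Early replicate 1 and 8428, 6176 and 10364 without Basal replicates 2, 3 and 4. In 20 simulated draws of unchanged groups against shared Basal libraries 0.05 regions passed per comparison on average, so their overlap of 0 gives no measure of what the shared libraries bring. Of the 2471 regions lower in Early, 1102 were also lower in Late (149 for independent lists), with 207 without Early replicate 2, 1936 without Early replicate 1 and 712, 487 and 692 without Basal replicates 2, 3 and 4. After median-of-ratios scaling 10896 of 14081 higher and 6895 of 11798 lower regions were shared (2060 and 1932 for independent lists). With the Basal libraries divided 2 and 2 between the comparisons, in 6 assignments, 508 to 4420 regions were higher in both (135 to 1015 for independent lists) and 33 to 189 lower in both (3.96 to 20.96). Dividing Basal does not remove what every Basal library has in common. Across the tested regions the fold changes of Early and Late had Pearson r = 0.753, Spearman rho = 0.753 and covariance 0.189. The simulated values were r = 0.464 and covariance 0.0171, a difference in covariance of 0.172. The draws had 1 spread per group and no differences between whole libraries, such as those in the share of reads in regions. This difference in covariance is therefore no measure of what lies beyond the shared libraries. With Basal divided 2 and 2, r was 0.568 to 0.633 and the mean covariance 0.165. Without Early replicate 2, r was 0.585. Of the 25280 regions higher in Late but not past the threshold in Early, 380 were also higher in Late than in Early when those groups were compared directly, and 145 of the 9278 corresponding lower regions were lower.

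The comparison of Reactivated with Late sets libraries with recall beside libraries without it. The 6 regions that led the rises were the same positions that led the falls in Late, in comparisons that share the Late libraries, whose highest region stood at 0.635 to 0.738 reads per base against 2.14 to 9.75 in the libraries of all other groups. Those on chromosome 2 lie close together, so the 6 are not separate places. How duplicate reads were handled is not given and sets the number of reads at such high regions. These rises are therefore not shown to go with recall. At chr2:98506396-98507470 the value was 141 ± 41.2 RPKM in Reactivated (SD, n = 3) against 4.96 ± 0.325 RPKM in Late (n = 4; log2 fold change 4.64 ± 0.35 SE, adjusted p = 2.07e-07), which is also above the 47.7 ± 10.4 RPKM of Basal. At chr9:35112799-35113174 it was 141 ± 45.9 RPKM in Reactivated and 6.85 ± 0.560 RPKM in Late (log2 fold change 4.21 ± 0.36 SE, adjusted p = 1.54e-06). The regions chr2:98502391-98503129, chr2:98505160-98505368 and chrX:139917553-139917648 rose by 2.95 to 3.49. At chr17:39979978-39985726 the value rose to 92.5 ± 6.71 RPKM in Reactivated (log2 fold change 2.62 ± 0.34 SE, adjusted p = 0.000618), but under quantile normalization its sign turned, to a log2 fold change of -0.55 (adjusted p = 0.00322), while its log2 fold changes on the deposited scale and after median-of-ratios scaling were 2.62 and 2.52. Quantile normalization keeps only the order of regions within a library. This region was the highest in Late replicates 2, 3 and 4, but below chr2:98506396-98507470 in each Reactivated library. The turned sign follows from that order and does not bear on the size of the rise in RPKM. Falls were led by chr5:9716395-9716607, from 4.11 ± 0.260 RPKM in Late to 0.775 ± 0.185 (log2 fold change -1.86 ± 0.27 SE, adjusted p = 0.00190), where Basal had 1.35 ± 0.358 and Early 0.782 ± 0.570 (0.522 without Early replicate 1). At chr17:81941615-81942269 the value fell from 4.20 ± 0.374 to 0.835 ± 0.396 RPKM (log2 fold change -1.86 ± 0.24 SE, adjusted p = 0.000578), with 0.916 ± 0.267 RPKM in Basal. The regions chr10:37960233-37960396, chr12:92442904-92443044, chr4:114059079-114059412 and chr12:97198746-97199017 fell by 1.67 to 1.74. Of these, chr12:92442904-92443044 lost its call in 10 of 28 alternative settings and chr10:37960233-37960396 in 6. The 6 falls rest on few reads, between 2 and 143 per library.

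**Figure D4:**
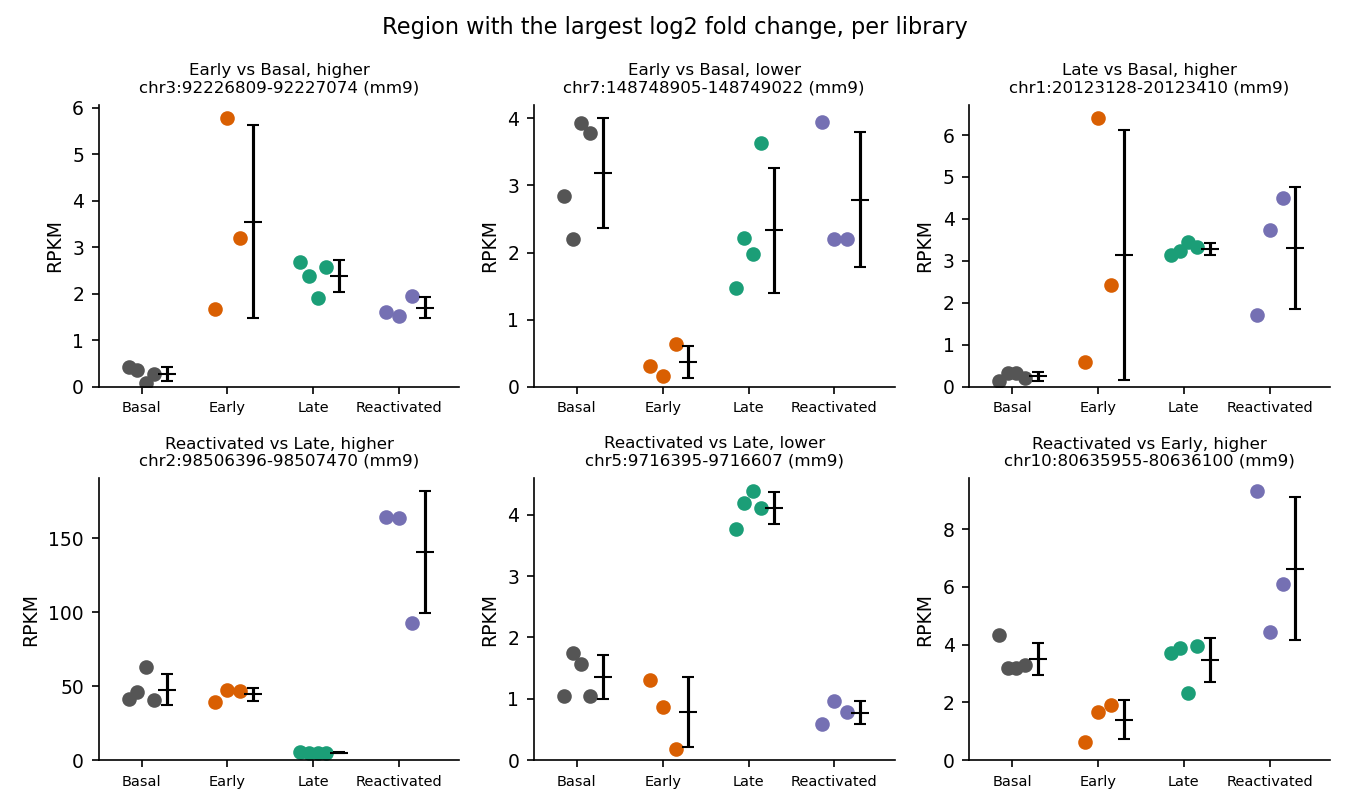
RPKM per library (points) with mean ± SD (bars) for the region with the largest log2 fold change in 6 comparison and direction pairs, mm9 coordinates as in the titles. The region on chromosome 2 had 141 RPKM in Reactivated and 4.96 in Late, and the region on chromosome 5 had 0.775 and 4.11.

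Fewer regions passed here than against Basal, 44 higher and 353 lower in Reactivated (limma, adjusted p under 0.05), with a median log2 fold change of 0.09. Median-of-ratios scaling gave 1033 higher and 687 lower, quantile normalization 98 and 547, and 24 higher and 324 lower regions were shared by the 3 scalings. Of the 353 lower regions 314 had been higher in Late than in Basal, and of the 44 higher regions 26 had been lower (84.5 and 2.65 for independent lists). After median-of-ratios scaling these were 421 of 687 and 902 of 1033, so the balance between the directions turned with the scaling. Without Early replicate 2 they were 476 and 101, without Early replicate 1 the second was 91, and leaving out 1 Late or Reactivated library gave 130 to 242 and 8 to 18. A shared group with opposite sign brings such overlap with no change at all. With the Late libraries divided 2 and 2 between the comparisons, in 6 assignments, 41 to 84 regions were higher in Late than in Basal and lower in Reactivated (4.10 to 14.5 for independent lists), and 6 to 8 were lower and higher (0.154 to 0.340). Dividing Late does not remove what every Late library has in common, such as the compressed range. This overlap therefore does not show a return with recall. The 10% of regions with the highest mean value had a median log2 fold change of 0.42, and the lowest 10% one of -0.02. The 6 tested regions on chrUn_random were among the lower ones, but they stood at the floor of 1 read in each Reactivated library, so their fold is not given. Across all tested regions the fold changes of Early against Basal and of Reactivated against Late, which share no libraries, had r = -0.213, rho = -0.235 and covariance -0.0338. Leaving out each library in turn gave r between -0.280 and -0.104, with -0.104 without Reactivated replicate 1 and -0.118 without Early replicate 1. The Late libraries stand apart in range and read totals. With them averaged to 1 sample, the fold changes stayed as they were (median 0.09), the other groups supplied the spread and 0 regions passed in limma (1769 at an unadjusted p under 0.05), whereas a fit of the Late and Reactivated libraries alone gave 5497 higher and 1220 lower. The count was 630 and 729 without Early replicates 1 and 2, 207, 214 and 203 without Late replicates 2, 3 and 4, and 215, 151 and 196 without Reactivated replicates 1, 2 and 3.

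Late was also compared with Early directly. The regions chr5:9716395-9716607 and chr17:81941615-81942269, which fell in Reactivated against Late, were higher in Late than in Early, with log2 fold changes of 1.96 and 1.95. At chr1:179105618-179105881 the value was 2.89 ± 0.458 RPKM in Late (SD, n = 4) and 0.397 ± 0.225 RPKM in Early (n = 3; log2 fold change 1.94 ± 0.25 SE, adjusted p = 0.000867), with 1.38 ± 0.579 RPKM in Basal and 1.34 ± 0.310 RPKM in Reactivated. These rises rest on few reads, between 2 and 143 per library. The largest falls were at chr2:98506396-98507470, chr9:35112799-35113174 and chr2:98502391-98503129, by 2.27 to 3.04. They also led the falls against Basal and move with the compressed range of Late. The highest region stood at 0.635 to 0.738 reads per base in Late libraries and at 2.14 to 2.57 in Early libraries. These falls are therefore not shown to be a change from Early to Late. In all, 534 regions were higher and 178 lower in Late (limma, adjusted p under 0.05), and 151 of the higher and 0 of the lower lay on chromosome 7, whose 3424 regions had a median of 0.31. All 6 tested regions on chrUn_random were among the higher ones, but they stood at the floor of 1 read in each Early library. Quantile normalization gave 2826 higher and 1247 lower and median-of-ratios scaling 845 and 456. Without Early replicate 2 the count was 10914, without Early replicates 1 and 3 228 and 175, without Late replicates 1 to 4 449, 229, 305 and 246. With Late averaged to 1 sample, and with the same fold changes, 0 regions passed in limma (3278 at an unadjusted p under 0.05).

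Reactivated differed from Basal at chr4:70407005-70407241, with 3.78 ± 2.21 RPKM in Reactivated (SD, n = 3) against 0.312 ± 0.278 RPKM in Basal (n = 4, 0.182 without Basal replicate 4; log2 fold change 2.32 ± 0.47 SE, adjusted p = 0.00343), at chr1:20123128-20123410, which also led the rises in Late (2.28), and at chr12:60186052-60186399 (3.24 ± 0.333 RPKM in Reactivated, 0.292 ± 0.165 RPKM in Basal; log2 fold change 2.26). The largest falls were at chr10:124436193-124436298, from 3.86 ± 1.06 to 0.573 ± 0.422 RPKM (0.351 without Reactivated replicate 1; log2 fold change -2.07 ± 0.29 SE, adjusted p = 0.00152), and at chr1:102702981-102703102 and chr6:66656589-66656704, both by 1.96. Early stood between Basal and Reactivated at the first of these falls, with 3.51 ± 0.878 RPKM. All regions named in this comparison rest on few reads, between 1 and 119 per library, with the lowest at 1 or 2 reads. In all, 41783 regions were higher and 8235 lower (limma, adjusted p under 0.05), with a median log2 fold change of 0.39. Median-of-ratios scaling gave 15361 higher and 18486 lower and quantile normalization 13857 and 14241. Among the 3368 regions of chromosome X, 1385 were higher and 10 lower. With the share of reads in regions as a covariate, whose values do not overlap between Reactivated and Basal, 0 regions passed in limma (22523 at an unadjusted p under 0.05). The count was 29599 and 27434 without Basal replicates 2 and 3, and 31401 and 19065 without Reactivated replicates 1 and 3.

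Reactivated against Early gave rises at chr10:80635955-80636100 (6.62 ± 2.48 RPKM in Reactivated and 1.40 ± 0.673 RPKM in Early, SD, n = 3 each; log2 fold change 1.92 ± 0.32 SE, adjusted p = 0.0224), at chr7:148748905-148749022, which led the falls in Early (1.92), and at chr6:3150778-3151666 (6.15 ± 1.60 RPKM in Reactivated and 1.35 ± 0.126 RPKM in Early; 1.82). It gave falls at chr10:124436193-124436298, chr12:15854366-15854471 and chr14:99269031-99269171, by 1.74 to 1.96. Outside chr6:3150778-3151666, with 58 to 357 reads per library, these rises and falls rest on few reads, between 1 and 76. The fall at chr12:15854366-15854471 lost its call in 7 of 28 alternative settings, and the other regions named here in 1 to 3. In all, 1625 regions were higher and 717 lower (limma, adjusted p under 0.05), with a median log2 fold change of 0.11, and 294 of the higher and 1 of the lower lay on chromosome 7. Median-of-ratios scaling gave 3233 higher and 1632 lower and quantile normalization 3484 and 1259. The count was 6, 29766 and 48 without Early replicates 1, 2 and 3, and 162, 593 and 95 without Reactivated replicates 1, 2 and 3. It was 1425 without Basal replicate 4, and 1196, 1192, 1002 and 1140 without Late replicates 1 to 4, which enter the fit through the shared estimate of spread.

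**Figure D5:**
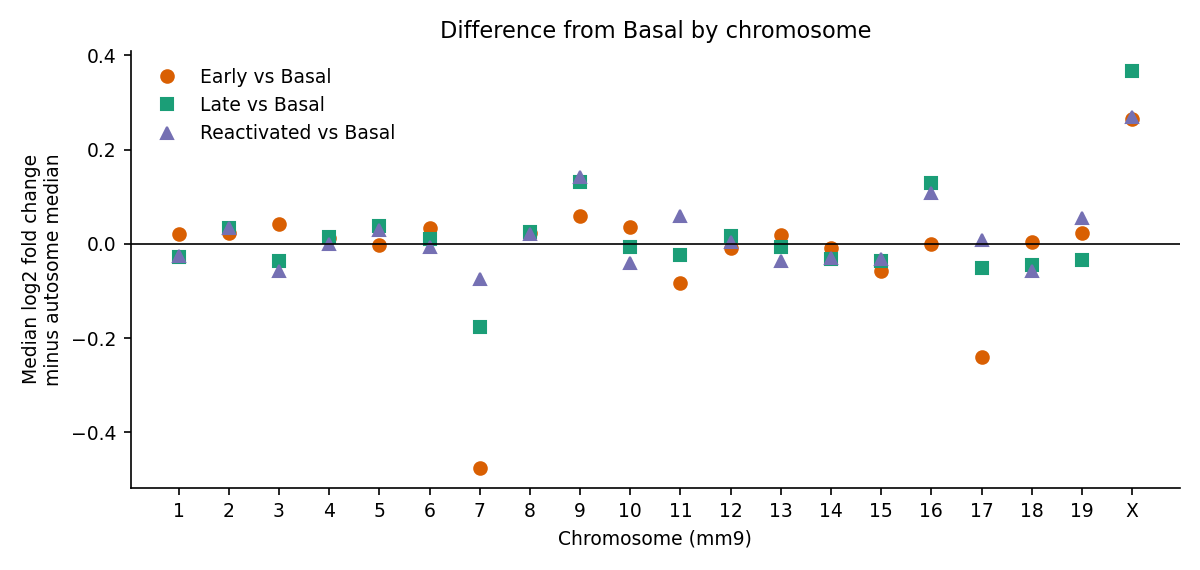
Median log2 fold change against Basal of the regions of each chromosome (mm9, chromosomes 1 to 19 and X) minus the median of all autosomal regions, for Early, Late and Reactivated. Chromosome 7 lies at -0.48 in Early, and chromosome X lies at 0.26, 0.37 and 0.27 in Early, Late and Reactivated.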

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

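All tests of explanations in this part, and the counts over other splits of the libraries, were written down only after the results they bear on had been seen. In 6 of 80 groups of 4 libraries at the named positions, and in 0 of 10 groups of library measures, 1 library lay far from the others (gap to the nearest library over the range of the group above 0.829), and chance gives about 5% of groups. At chr3:110691792-110692046 Basal replicate 2 had 0.725 RPKM and the other Basal libraries 0.0725 to 0.145 (gap over range 0.843). At chr2:148538786-148538946 Basal replicate 4 had 1.73 and the others 2.88 each (1.00). At chr10:80635955-80636100 Basal replicate 1 had 4.32 and the others 3.18 to 3.30 (0.875), and Late replicate 3 had 2.33 and the others 3.71 to 3.96 (0.874). At chr12:15854366-15854471 Basal replicate 1 had 4.74 and the others 1.40 to 1.75 (0.833). At chr12:92442904-92443044 Late replicate 4 had 5.02 and the others 2.48 to 2.77 (0.848).

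For Late against Basal, with the Late libraries as 4 samples, 1 of 35 splits of the libraries, the real one, gave as many regions (51582), and the highest other gave 0. The same held for Reactivated against Late (397 regions, 1 of 35 splits, highest other 3), Late against Early (712, 1 of 35, highest other 1) and Reactivated against Basal (50018, 1 of 35). In the last, the highest other split gave 19450 regions, with Basal replicates 2, 3 and 4 against Basal replicate 1 and the Reactivated libraries, which points to a structure among the Basal libraries. For Early against Basal chance was not excluded. There 2 of 35 splits gave as many regions as the real groups (21307), and the highest other, with 22179, put Basal replicate 1 with Early replicates 2 and 3. The splits that involve Late count its 4 libraries as separate samples. With Late averaged to 1 sample, which leaves the fold changes as they were and takes the spread from the other groups, 0 regions passed in Late against Basal, Reactivated against Late and Late against Early (limma, 24989, 1769 and 3278 at an unadjusted p under 0.05). For Reactivated against Early the 10 splits are too few for a share under 0.05 (real value 2342, highest other 2, 1 split as large).

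The values of the Late libraries had a compressed range. Less signal over background in Late stays open. Of the 10 other libraries, 5 had both a lower share of reads in regions and a wider range than every Late library. That share counts all listed regions, weak ones too, and the median RPKM was 1.36 in Late against 1.03 in Basal. It can also depend on how reads were filtered, so this test cannot decide. A difference in the authors' processing of the Late libraries is a candidate explanation: the lowest Late library had 69 regions of chrUn_random above 1 read, and the highest other library 0. The 99 regions there held 3139 to 4393 reads in Late and 99, the floor of 1 read each, in every other library. Reads on chrUn_random were thus handled differently in Late. Whether such handling also compressed the range was not tested. The highest region stood at 0.635 to 0.738 reads per base in the Late libraries and at 2.14 to 9.75 in the other 10, a difference that goes with these marks. The state 5 days after conditioning cannot be told apart from a difference in processing. The Late libraries are the ones with such processing marks and the only ones collected on day 5 without recall (ratio 4.23 in Late, lowest Reactivated library 8.17).

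Many more regions were higher than lower in Early than in Basal, 88.4% of those past the threshold. A swap of the labels of Early replicate 1 and Basal replicate 1 was argued against, since the lowest correlation of Basal replicate 1 with another Basal library was 0.673 and its highest with Early replicates 2 and 3 was 0.583. The excess may come from differences in the share of reads in regions, as with that share as a covariate 57.0% were higher. It may rest on Early replicate 2, the library with the highest share, since 1227 regions passed without it, 62.8% of them higher, against 21307. A difference between the groups themselves stays open, as both tests also remove signal that goes with the groups.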

How the results depend on the processing

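The tests with Late averaged to 1 sample, the share of reads in regions as a covariate, limma voom on recovered reads, and without chrUn_random and chromosome Y, and the leaving out of libraries for the share of reads in regions, were chosen only after the results had been seen. At a median of 25 to 47 reads per region, changes of 2-fold were recovered in 8% to 26% of simulated cases, a share that holds for a simulation with few changed regions and does not carry over to comparisons with many calls. Of 1512 values of the named regions under alternatives, 1443 kept their direction and call, 68 lost the call and 1 turned its sign: chr17:39979978-39985726 in Reactivated against Late, at -0.55 under quantile normalization. The named regions had been chosen as the largest called changes, so kept calls follow in part from the choice. Of 54 named results, 54 kept their call under median-of-ratios scaling, 35 lost it with Late averaged and 7 with the covariate. Where a value below differs from the reported one, the cause was not tested, except that fewer regions were tested above the median and fewer samples entered with Late averaged. There the lone Late sample is assumed to vary like the other groups, and the fold changes were the same. Count-model tools on recovered reads, gene lists, promoter classes and motifs were planned and not run. The library weights did not converge (Early replicate 3 had a weight of 127, the others 0.102 to 1.27), so those counts carry no meaning of their own.

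Numbers of regions past the threshold moved over 1.5-fold as follows. In Early against Basal (21307) they were 14171 with regions above the median, 6370 in a fit of these groups alone, 83509 with weights, 10991 with Late averaged and 13457 with the covariate. In Late against Basal (51582) they were 27778 above the median, 81432 with weights, 0 with Late averaged (limma, 24989 at an unadjusted p under 0.05) and 31606 with the covariate. In Reactivated against Late (397) they were 261 with pseudocount 0.1, 641 without filter, 118 above the median, 645 with quantile normalization, 1720 with median-of-ratios scaling, 6717 in a fit of these groups alone, 5632 with weights, 0 with Late averaged (limma, 1769 at an unadjusted p under 0.05) and 2200 with the covariate. In Late against Early (712) they were 229 above the median, 4073 with quantile normalization, 1301 with median-of-ratios scaling, 89381 with weights, 0 with Late averaged (limma, 3278 at an unadjusted p under 0.05) and 5939 with the covariate. In Reactivated against Basal (50018) they were 28098 with quantile normalization, 78637 with weights and 0 with the covariate (limma, 22523 at an unadjusted p under 0.05). In Reactivated against Early (2342) they were 4743 with quantile normalization, 4865 with median-of-ratios scaling, 861 in a fit of these groups alone, 69682 with weights, 4695 with limma voom and 13 with Late averaged.

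Leaving out 1 library gave 1227 to 46005 regions in Early against Basal, 34908 to 66072 in Late against Basal, 151 to 729 in Reactivated against Late, 175 to 10914 in Late against Early, 19065 to 70098 in Reactivated against Basal and 6 to 29766 in Reactivated against Early. The correlation of the fold changes of Early and Late was 0.585 to 0.777, and that of Early against Basal with Reactivated against Late kept its sign, at -0.280 to -0.104. The share of reads in regions, -0.749 points in Late minus Early, ranged from -3.79 without Early replicate 1 to 3.19, the other direction, without Early replicate 2. With the replicate number as a replicate block, 11671, 45041, 239, 329, 35857 and 478 regions passed in Early against Basal, Late against Basal, Reactivated against Late, Late against Early, Reactivated against Basal and Reactivated against Early. The numbers do not pair the libraries: over 19 pairs with the same number, deviations correlated at -0.260 to 0.0687, and 0 libraries correlated best with their own number.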

Other observations

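All tests in this part were chosen only after the results had been seen. Chromosome X held 1.79% ± 0.147 of the reads in regions in Basal (SD, n = 4), 1.97% ± 0.286 in Early (n = 3), 2.16% ± 0.0499 in Late (n = 4) and 2.06% ± 0.147 in Reactivated (n = 3). The median of its regions relative to the autosomes was -0.22 ± 0.07 in Basal, 0.03 ± 0.24 in Early (0.30 in replicate 2 and -0.16 and -0.05 in replicates 1 and 3), 0.13 ± 0.04 in Late and 0.08 ± 0.10 in Reactivated (log2). Late lay above Basal in 4 of 4 libraries (exact permutation p = 0.0286, the smallest that 4 against 4 allow, adjusted over 18 tests 0.129). The same measure did not separate Early from Basal (exact permutation p = 0.114, adjusted 0.171). Reads on chromosome Y, from 3 regions, were scaled to the same number of reads in regions for each library. They stood at 15.0 ± 2.73 in Basal, 7.34 ± 1.66 in Early, 16.5 ± 2.17 in Late and 12.3 ± 2.19 in Reactivated (SD). Early (6.24 to 9.26) lay below Basal (11.2 to 17.7), and Late (13.3 to 18.0) overlapped it. Whether the pools differed in the sex of the mice was not tested, and 3 regions are too few to decide it. The 10% of regions with the highest mean value had a median log2 fold change of 0.63 in Reactivated against Basal and the lowest 10% one of 0.33, with 0.39 over all regions. In Late against Basal they stood at 0.20 and 0.35, with 0.28 over all regions. After median-of-ratios scaling the highest and lowest 10% stood at 0.21 and 0.03 in Reactivated against Basal. In Late against Basal they then stood at -0.13 and 0.11, so the sign of the highest 10% turned.

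Regions of chromosome 7 were lower in Early than in Basal. A trend with how densely regions lie was argued against as the whole cause, though not as a part: the median of 30 windows of 5 Mb lay -0.56 from all windows of other autosomes and still -0.30 from those with the nearest number of regions, with 80.0% over 0.1 below theirs (6 were not). Gain or loss of a segment stays open: the 10 windows between 0 and 55 Mb (40 to 45 Mb held too few regions) lay -0.97 to -0.54 from theirs, and the other 20 -0.42 to 0.24 with a median of -0.22. Steps of like size along a chromosome were found elsewhere, with the largest at 0.73 on chromosome 4, 0.59 on chromosome 5, 0.55 on chromosomes 7 and 11 and 0.52 on chromosome 16. Gene density stays open as a part of the cause. The 4 autosomes with most protein-coding genes per Mb (7, 11, 19 and 17, 11.1 to 13.3) had odds ratios of 13.9, 1.92, 2.09 and 5.07 for lower regions, and the others at most 1.06. As the whole cause it was argued against. Chromosomes 7 and 11 held 13.3 and 13.2 genes per Mb, but their median log2 fold changes lay -0.48 and -0.08 from that of the autosomes. On chromosome 19 this was 0.02. Base composition, which was not tested without a genome sequence of this build, stays open. So do a change of the whole chromosome and a difference between the groups.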
